A study of Mus musculus with 18 samples.

How the data were processed

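The series holds 18 libraries from primary astrocytes of newborn C57BL mice of pooled sexes, plated at 1300000 cells per dish. Per the labels, untreated cells were harvested after 120 h, and treated cells after 96 h of culture plus 24 h, or 72 h plus 48 h, with 20 ng/ml TNFα and 0.25 ng/ml IL-1β. Each of the 6 groups (RNA or ribosome footprints, each untreated, 24 h and 48 h) held 3 batches, named A, B and C. Per the labels' protocols, lysates contained cycloheximide and were divided into an RNase I-digested part, from which footprints of 26 to 34 nt were selected on a gel, and an undigested part for RNA-seq with a stranded total RNA kit. The label of the molecule, however, reads polyA RNA, and which of these applied was not resolved.

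Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 and counted with featureCounts. No versions were stated, and how counts were normalized, how the batches were combined and how fold changes were computed is not given in the sources used here. The authors deposited 1 table of log2 fold changes against untreated cells, with 6 value columns (RNA, footprints and translation efficiency at 24 h and 48 h), for 12205 genes, per the file headers. The header of the translation efficiency columns names no scale, and they were read as log2 because they lie within 0.1 of the footprint minus the RNA value in 79.5% of genes at 24 h and 78.0% at 48 h. Further sheets that the authors deposited in the same workbook repeat the log2 values for 5 gene sets of the study, equal to those in the main table, and give p-values for these sets. The authors wrote these as signed scores, as deposited: a minus sign was read as a lower set, and the size as the p-value. The test behind the authors' p-values is not given in the sources used here. No counts or levels per library are in these files, so the depth of each library, the precision it gives, and the spread between batches are unknown.

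Gene identifiers were checked against the table of gene names (12201 of 12205 matched), and 31 symbols were replaced by the name given there. Positions came from RefSeq on GRCm38.p6, matched by symbol for 12007 genes. Gene span was the distance from start to end, and gene density the number of protein-coding genes in a window of 1000000 bp. No value was missing, and no filter was applied. Genes with near-identical copies, such as the Serpina3, H2 and Gbp families and ribosomal protein genes with processed pseudogenes, may share reads, and their values are uncertain to that extent.

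A plan with a test across batches had been fixed before the data were examined, with a fallback for files holding only means. The fallback applied: no test was possible, and for each comparison genes with an absolute log2 value of at least 1 were counted. The comparisons were RNA, footprints and translation efficiency at 24 h and 48 h against untreated, and 48 h against 24 h as the difference of both values. For 34 gene lists (28 of pathways and 6 of markers of other cell types), also fixed before the data were examined, the median of the measured members was ranked among the medians of 10000 random lists of the same size drawn from all genes. Random lists could not be matched on expression, as no levels are in the files. Lists outside the central 95% are said to stand apart, a limit chosen later, as were 9 added gene lists. Lists with fewer than 5 measured members were not ranked, and medians cover the measured members alone. Interquartile ranges are over the members of a list and describe genes, not replicates.

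The genes named in the text followed a rule fixed beforehand. For each of the 6 comparisons with untreated cells it took the 5 highest and 5 lowest among genes with the same sign in RNA and footprints, up to 3 members of each list that stood apart, and Lcn2, C3, Gfap, Serpina3n, Nfkbia, Nos2, Ccl2, Cxcl10, Il6, Aqp4, Slc1a2 and Gja1, and the 12 genes named on the authors' deposited sheet of p-values. It gave 190 distinct genes, from which the text names some. The remaining named genes (such as Vim, Slc1a3, Aldh1l1, P3h2, Adgre1, Dkk1, the markers of cell types too few to rank and the genes of the closing observations) were chosen after their values were seen.

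The agreement between RNA and footprints was described with Pearson's r, Spearman's rho and a total least squares slope across genes. Chance correlation through the shared untreated libraries was simulated with unchanged groups. The ranking of lists was tested on simulated data built by shuffling the RNA values at 24 h over 12205 genes. Lists whose members vary together were therefore not simulated. The ranking called 4.22% of unshifted lists, 52.5% of lists shifted by 0.25, 90.2% at 0.5 and 99.7% at 1. A trend that rose with gene density and, more weakly, with gene span was then added to shuffled translation efficiency values at 24 h. With it 6.83% of lists were called against random lists and 4.17% against lists matched on density and span in 25 classes. The deposited translation efficiency at 24 h falls with span (rho -0.309), so 6.83% does not measure how often the real trend leads to a call.

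Alternatives planned beforehand that could be run were a threshold of 1.5 times, columns shifted to a median of 0, leaving out genes past 5 in any column for the counts, leaving out genes in more than 1 list, and, for the correlation, only genes past the threshold. Added after the data were examined were list means, random lists matched on density and span, lists and correlations without genes past 5, and footprint minus RNA values in place of the deposited translation efficiency. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.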

Results

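Primary astrocytes from newborn C57BL mice were left untreated or exposed to the inflammatory cytokines TNFα (20 ng/ml) and IL-1β (0.25 ng/ml) for 24 h or 48 h before harvest. Each lysate was divided between RNA-seq, which measures mRNA abundance, and ribosome profiling, in which RNase I leaves the mRNA fragments covered by ribosomes (footprints of 26 to 34 nt). The 18 libraries fell into 6 groups of 3 batches: untreated, 24 h and 48 h, each for RNA and for footprints. The authors' deposited table holds 1 log2 value per gene and comparison for 12205 genes, in RNA, in footprints and in translation efficiency, the change in footprints relative to RNA. There were no replicate values, so no difference below was set against the spread between batches, and the depth of each library is unknown. Genes are therefore called higher or lower by size alone, at a log2 value of at least 1 or at most -1, and a list of genes is said to stand apart when its median lay outside the central 95% of 10000 random lists of the same size. That limit was chosen after the values were seen. If genes varied independently, chance would give 1.6 of the 32 ranked lists per comparison. Lists whose members vary together can stand apart more often, and how often could not be measured without replicate values.

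After 24 h the RNA medians of chemokine, interferon-stimulated, antigen presentation and complement genes lay above those of random lists, and the medians of cell cycle and homeostatic astrocyte genes lay below. The authors' deposited table had the largest RNA values for Acod1 (12.95), which makes itaconate, the chemokine gene Cxcl9 (11.99), the acute phase gene Saa3 (11.74), Cxcl11 (11.29) and Nos2 (10.68), the inducible nitric oxide synthase. On GRCm38.p6, Acod1 lies on chromosome 14 from 103047012 to 103056573, and Nos2 on chromosome 11 from 78920787 to 78960226. The lowest values in the authors' deposited table were those of Fgfbp1 (-6.43), the lens water channel gene Mip (-5.82), Tll2 (-5.27), Sncb (-5.14) and Oca2 (-5.06). Of 12205 genes, 920 were higher and 1166 lower by at least 1, together 17.1%.

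Among the lists fixed beforehand, chemokines and interferon-stimulated genes had the highest medians. The 18 measured chemokines had a median RNA value of 8.31 at 24 h (interquartile range 3.40 to 10.24), and 16 of them were higher by at least 1. All 46 interferon-stimulated genes passed 1, with a median of 3.59, and among them Gbp4 (9.18) and Gbp6 (7.72), which code for guanylate-binding proteins, were far higher in the authors' deposited table. In the 20 genes of NF-kB feedback and signalling the median was 2.66. Of these, 16 were higher, including the inhibitors Nfkbia (3.14) and Tnip3 (6.12), while the adaptor gene Traf1 was lower at -2.85 in the authors' deposited table. Traf1 is a known target of NF-kB, and its value is uncertain, as no counts were there to check it. MHC class I antigen presentation (22 genes) had a median of 2.39 with 20 members higher, led by H2-Q6 at 7.25 in the authors' deposited table. Synthesis of nitric oxide and prostaglandins (10 genes) had a median of 2.55 with 6 members higher. Ptgs2, which codes for cyclooxygenase, was at 5.58 in the authors' deposited table. Complement (13 genes) had a median of 1.63 and 8 members higher, and C3 stood at 5.50 and the factor B gene Cfb at 5.58 in the authors' deposited table. Cytokines and growth factors (21 genes) had a median of only 0.57, although Csf3 (10.29), Il19 (6.78) and Il6 (6.84) were far higher in the authors' deposited table. The medians of all 7 lists lay above all 10000 random lists. These medians and counts cover the measured members alone. If genes silent in untreated cells entered the deposited values only when induced, they lie too high.

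Astrocyte genes divided within their lists. Of the 13 pan-reactive genes, 7 were higher and 4 lower by at least 1 in RNA at 24 h (median 2.19). Lcn2 (7.53) and Serpina3n (2.19) were higher, but the intermediate filament genes Gfap (-1.79) and Vim (-1.38) were lower in the authors' deposited table. The A1 list (10 genes) had a median of 2.18 with 6 higher, and the A2 list (12 genes) a median of 1.15 with 6 higher. Homeostatic astrocyte genes (28) had a median of -0.81, below all random lists, with 8 lower and 2 higher. The potassium channel gene Kcnj10 (-2.75), Aldoc (-2.69) and Aldh1l1 (-1.23) were lower, and the glutamate transporter genes Slc1a2 (2.17) and Slc1a3 (1.05) were higher in the authors' deposited table. The same table, the authors' deposited table of log2 values, placed the water channel gene Aqp4 at 0.32 and the gap junction gene Gja1 at -0.50.

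The cell cycle lists had RNA medians below 0 at 24 h. Of 34 mitosis genes, 31 were lower by at least 1 (median -1.58, interquartile range -1.85 to -1.39), with Cenpf at -2.23 and Aurkb at -2.03 in the authors' deposited table. DNA replication (40 genes) had a median of -0.68 with 14 lower, among them the polymerase gene Pold1 at -1.92 in the authors' deposited table. Both medians lay below all random lists. Apoptosis genes (36) had a median of 0.35 with 11 higher, including Casp4 (5.73) and the inhibitor gene Birc3 (3.64) in the authors' deposited table, and antioxidant and metal response genes (25) a median of 0.38 with 9 higher. Smaller shifts that stood apart were those of the ribosomal proteins of the small (0.22) and large (0.21) subunits, TOP translation factors (0.31), aminoacyl-tRNA synthetases (0.34), stress response genes (0.23), nuclear-encoded oxidative phosphorylation subunits (-0.21) and extracellular matrix (-0.24). With list means in place of medians none of these 7 stood apart in RNA at 24 h, at percentiles of 83.5, 85.3, 87.7, 91.1, 96.5, 2.64 and 54.1. Inside the random range were matrix metalloproteinases (0.02, but above it by their mean at a percentile of 99.97), glycolysis (-0.10), cholesterol synthesis (0.17), histones (-0.24), mitochondrial ribosomal proteins (0.08) and mitochondrially encoded proteins (0.31).

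In footprints at 24 h the inflammatory and reactive astrocyte lists lay above random lists, and the cell cycle and homeostatic astrocyte lists below. Aminoacyl-tRNA synthetases (median 0.22) and oxidative phosphorylation subunits (0.13), apart in RNA, lay inside the random range in footprints. Mitochondrial ribosomal proteins (0.22) and cholesterol synthesis (0.25) were inside it in RNA and stood above it in footprints, but neither by their means (percentiles 91.3 and 90.0) nor against lists matched on gene density and span (95.8 and 97.0). The authors' deposited table had the largest footprint values for the inflammasome sensor gene Nlrp3 (11.41), Cxcl2 (11.21), Vnn3 (9.49), Nos2 (8.98) and Ccl5 (8.70), and the lowest for Mip (-7.09), the thyroid hormone transporter gene Slco1c1 (-6.00), Chdh (-5.76), Adamts18 (-5.69) and Wnt2b (-5.51). In footprints 961 genes were higher and 1062 lower by at least 1. Chemokines had a median of 6.63, interferon-stimulated genes 3.57 with all 46 higher, NF-kB genes 3.11, antigen presentation 2.63, nitric oxide and prostaglandin synthesis 2.62, complement 1.46, A1 genes 1.92, A2 genes 1.40, pan-reactive genes 1.77 and cytokines 0.81. Mitosis had a footprint median of -1.86 with 33 of 34 lower, DNA replication -0.80 and homeostatic astrocyte genes -0.83. Apoptosis reached 0.78 and the antioxidant list 0.76. The ribosomal proteins stood higher in footprints than in RNA, at 0.76 for the small and 0.65 for the large subunit. Gfap was at -2.07, Slc1a2 at 1.59 and Aqp4 at -0.08 in footprints in the authors' deposited table.

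At 48 h the inflammatory, reactive, homeostatic and cell cycle lists stood apart again. The authors' deposited table had the largest RNA values for Saa3 (12.29), Acod1 (11.78), the protease inhibitor gene Serpina3f (11.03), Cxcl5 (10.89) and Saa2 (10.61), and among the lowest Mip (-9.89), 2210011C24Rik (-8.20), Lect1 (-6.75) and the collagen gene Col8a2 (-6.23). In RNA 990 genes were higher and 1259 lower, and in footprints 992 and 1063. The RNA medians were 7.12 for chemokines, 2.57 for interferon-stimulated genes (42 of 46 higher), 2.26 for NF-kB genes, 1.87 for antigen presentation, 1.82 for complement, 2.48 for nitric oxide and prostaglandin synthesis, 2.44 for pan-reactive, 1.93 for A1 and 1.26 for A2 genes. Those below 0 were mitosis (-1.49, 30 of 34 lower), DNA replication (-0.64) and homeostatic astrocyte genes (-0.72, 11 of 28 lower). Gfap was at -2.11, Kcnj10 at -2.95, Lcn2 at 7.72 and C3 at 6.38 in RNA in the authors' deposited table. Mitochondrially encoded mRNAs (9 genes) stood above random lists at a median of 0.64, but not by their mean (percentile 92.5).

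In footprints at 48 h the authors' deposited table had Nlrp3 (10.71), Vnn3 (10.64), Cxcl2 (10.56), Gm14275 (9.34) and Saa3 (8.88) highest and Col8a2 (-6.59), Col4a4 (-6.57), Oca2 (-6.15), 3110035E14Rik (-5.71) and Nppc (-5.67) lowest. Medians were 5.70 for chemokines, 2.57 for interferon-stimulated genes, 2.95 for NF-kB genes, 2.08 for antigen presentation, 1.61 for complement, -0.91 for homeostatic astrocyte genes and -1.68 for mitosis (32 of 34 lower). Matrix metalloproteinases and their inhibitors (22 genes) had a median of 0.49 with 9 higher and 3 lower, led by Mmp9, which codes for a gelatinase, at 7.14 in the authors' deposited table. Without the genes whose value passed 5 in any column, that list no longer stood apart (percentile 95.9). Glycolysis (22 genes) had a footprint median of 0.29, which stood apart by its median (percentile 98.9) and not by its mean (72.7).

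**Figure D1:**
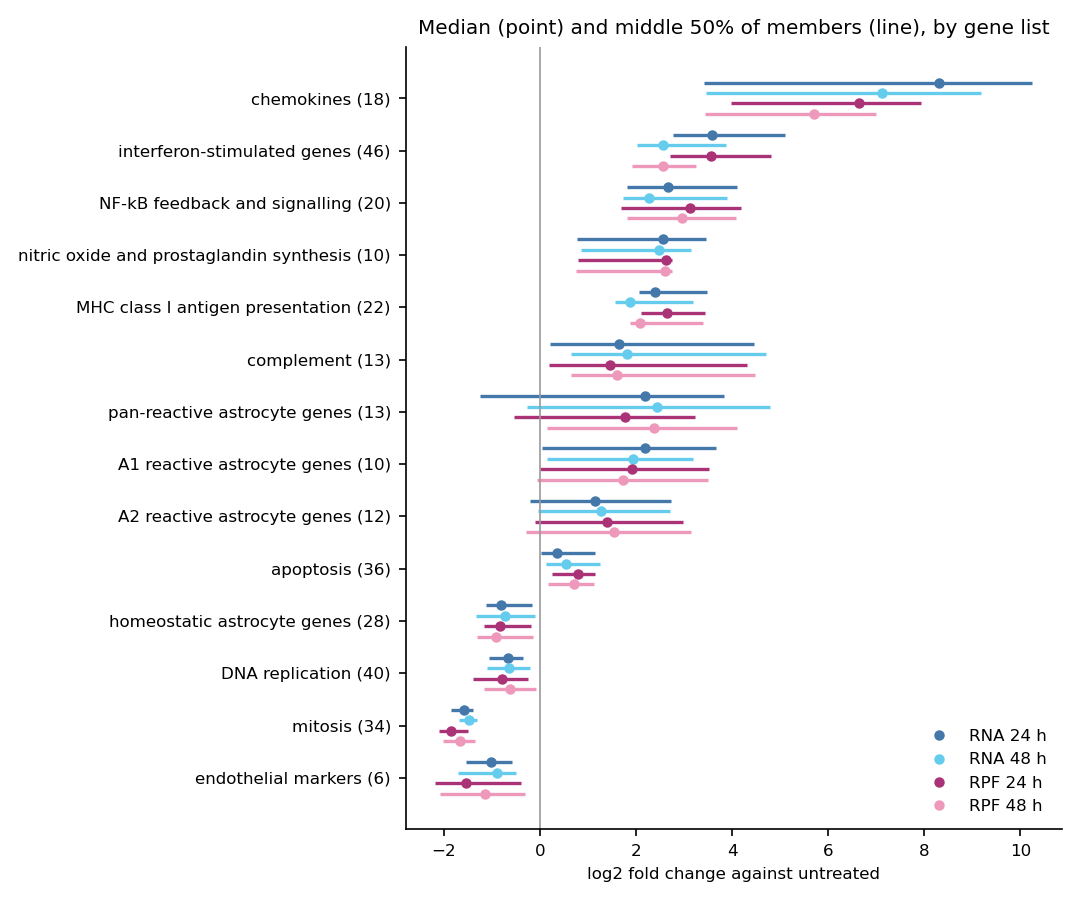
Median log2 fold change against untreated cells (point) and interquartile range of the members (line) for 14 gene lists, in RNA and footprints at 24 h and 48 h, with the number of measured members in brackets. Chemokines lie highest (8.31 in RNA at 24 h) and mitosis genes lowest (-1.86 in footprints at 24 h).

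Each gene's value at 48 h was then set against that at 24 h. The median differences of interferon-stimulated, chemokine and antigen presentation genes lay below 0, and that of complement genes above 0. Interferon-stimulated genes differed by a median of -0.95 in RNA and -0.98 in footprints, chemokines by -0.41 and -0.39 and antigen presentation by -0.47 and -0.33, all below all random lists. Random lists were drawn from all genes, whose RNA differences had quartiles of only -0.12 and 0.12. Genes far from 0 at 24 h may differ more, and lists of like 24 h value were not drawn. In RNA 20 of 46, 5 of 18 and 1 of 22 members differed by at most -1, and 6 of the chemokines lay above 0. Cxcl10 stood at 8.36 and then 6.26, and Cxcl9 at 11.99 and then 9.04 in RNA in the authors' deposited table. Complement differed by 0.24 in RNA and 0.33 in footprints, at percentiles of 99.96 and 100, with 8 and 11 of 13 members above 0 and 0 past 1. In RNA NF-kB genes (-0.25), A1 genes (-0.36) and cytokines (-0.12) also lay below random lists, and mitosis (0.11) and DNA replication genes (0.08) above. In footprints NF-kB genes (-0.10) and cytokines (-0.07) lay inside the random range. Cholesterol synthesis differed by -0.22 in RNA and mitochondrially encoded mRNAs by 0.31. Past 1 in either direction were 190 genes in RNA (77 higher and 113 lower at 48 h) and 219 in footprints (89 and 130). Without genes past 5 in any column, 58 were higher in footprints. The farthest in RNA were Adgre1, a macrophage marker, at 6.98, and Mip, at -4.06, and in footprints Wfdc17 at 5.44 and the Wnt inhibitor gene Dkk1 at -5.39. These differences were picked after the values were seen, though Mip and Wfdc17 also fell under the fixed rule. Adgre1 at 24 h stood at 0.57 in RNA, 0.73 in footprints and -1.79 in translation efficiency in the authors' deposited table, values that do not add up. The footprint value of Wfdc17 at 24 h was 0.05 beside 7.11 in RNA in the authors' deposited table. That of Dkk1 at 48 h was 0.23 beside 3.16 in RNA and -0.82 in translation efficiency in the authors' deposited table, so its 3 values do not add up.

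The 24 h and 48 h values correlated across genes at r = 0.966 in RNA, 0.949 in footprints and 0.808 in translation efficiency, though genes are not independent replicates. Both times were compared with the same untreated libraries, and unchanged groups simulated against shared controls gave r = 0.504, 0.494 and 0.499. The simulation gave all groups the same spread, which fixes r near these values whatever the data. The covariance was 1.35 in RNA, 1.16 in footprints and 0.193 in translation efficiency, against simulated values of 0.0164, 0.0236 and 0.0262. In RNA 838 genes were higher at both times and 1003 lower, where independent lists would share 74.6 and 120. In footprints the counts were 839 and 884 against 78.1 and 92.5. The simulated spread was the same for all genes, so noisier genes are left out and the simulated covariances may be too low. With no values per library the controls could not be split, so part of the excess may come from them.

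Footprint values tracked RNA values over most of the measured genes. Across 12205 genes Pearson's r was 0.918 at 24 h and 0.909 at 48 h (Spearman's rho 0.780 and 0.754), with total least squares slopes of 0.939 and 0.918. Among genes past 1 in RNA or footprints the sign was the same in 99.0% at 24 h and 98.1% at 48 h. Of 1589 genes past 1 in both at 24 h, all but 1 went the same way. The exception was P3h2, a collagen-modifying enzyme gene chosen after its values were seen, with 1.08 in RNA and -1.18 in footprints in the authors' deposited table. Over the 82 ribosomal protein genes r was 0.133 at 24 h and 0.0775 at 48 h, within a narrow range of RNA values (0 genes past 1 at 24 h and 2 at 48 h), and other genes of like range were not compared.

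**Figure D2:**
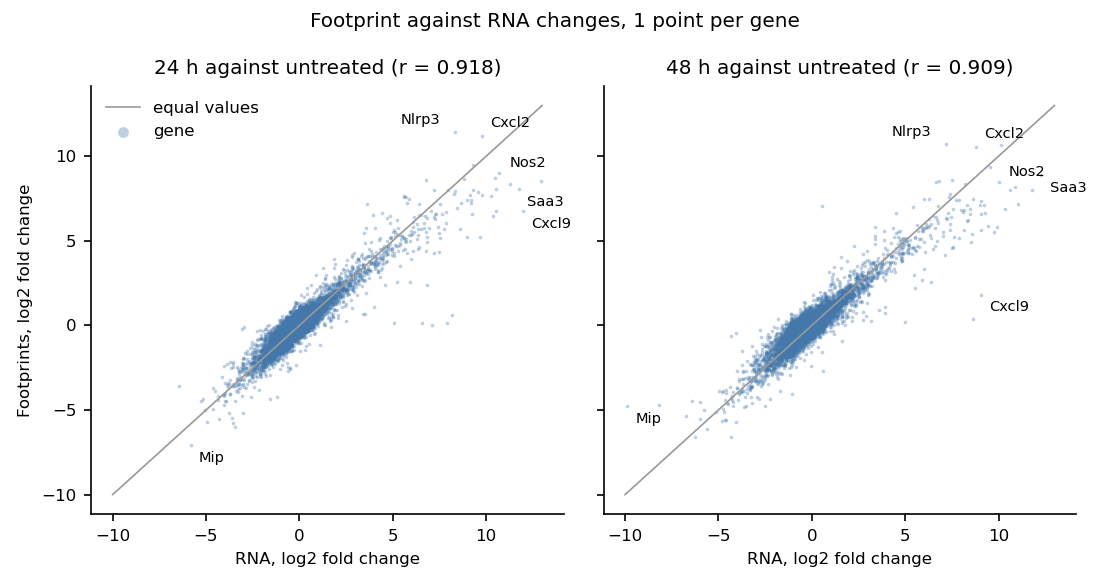
Footprint log2 fold change (vertical) against RNA log2 fold change (horizontal) for 12205 genes at 24 h and 48 h, 1 point per gene, with a line of equal values. The points follow the line (r = 0.918 and 0.909), and Cxcl9 lies below it, at 11.99 in RNA and 6.77 in footprints at 24 h in the authors' deposited table.

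In translation efficiency at 24 h the medians of ribosomal proteins and of oxidative phosphorylation subunits lay above random lists, and those of chemokines and mitosis genes below. Only 9 of the 82 ribosomal proteins were higher by at least 1. The 34 small subunit proteins had a median of 0.53 (interquartile range 0.32 to 0.78) and the 48 large subunit proteins a median of 0.50, both above all random lists. Rps10 (0.87), Rpsa (0.84) and Rps26 (1.36) were among the higher ones in the authors' deposited table, while Rpl13a (-0.90) and Rps27a (-0.58) lay below 0. Nuclear-encoded oxidative phosphorylation subunits (77) had a median of 0.28 with 9 higher by at least 1, including Atp5g2 (1.66), Uqcr11 (1.40) and Ndufa11 (1.29) in the authors' deposited table. Mitochondrial ribosomal proteins (77) had a median of 0.17 and oligodendrocyte markers 0.39. These last lists did not stand apart against lists matched on gene density and gene span (percentiles 83.3 and 96.7). In all genes, translation efficiency correlated with the number of protein-coding genes nearby at rho = 0.330. The other lists above had percentiles of at least 99.76 among such matched lists.

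**Figure D3:**
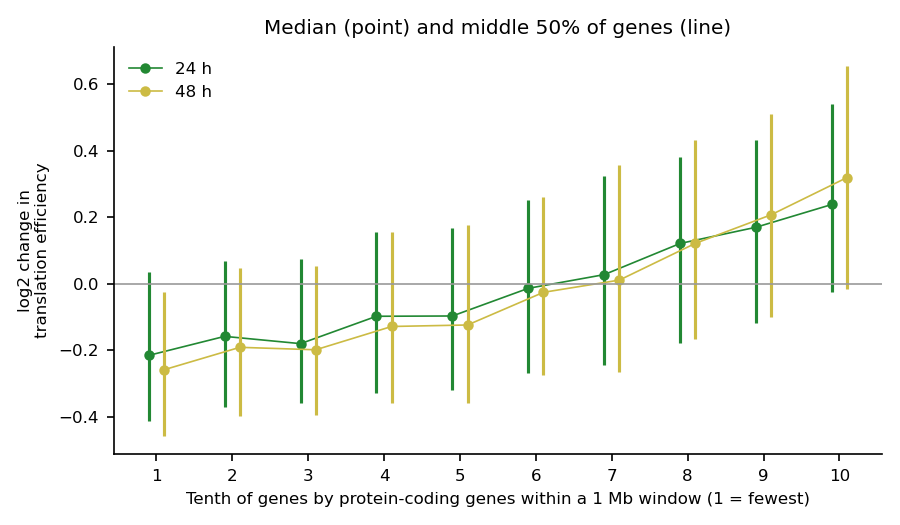
Median log2 change in translation efficiency (point) and interquartile range (line) at 24 h and 48 h for 10 equal groups of genes ordered by the number of protein-coding genes within a window of 1000000 bp. The median goes from -0.22 to 0.24 at 24 h and from -0.26 to 0.32 at 48 h.

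Below 0 at 24 h were chemokines (-0.63, 7 of 18 lower by at least 1), pan-reactive astrocyte genes (-0.37), mitosis (-0.35), interferon-stimulated genes (-0.25) and matrix metalloproteinases (-0.25). Leaving out genes past 5 in any column ended this for chemokines, pan-reactive genes, interferon-stimulated genes and metalloproteinases (percentiles 91.0, 46.1, 4.23 and 5.39). The pan-reactive list also lost it without genes in more than 1 list (5.99) or by its mean (7.37). Antigen presentation genes lay inside the random range at 24 h and 48 h. Against lists matched on gene density and span they lay below it (percentiles 0.11 and 0.92). Single genes ranged widely. The authors' deposited table held the highest translation efficiency values for Fam169a (2.76), Fgfbp1 (2.56), Tmem132e (2.52), Arl5c (2.48) and Filip1 (2.40), and the lowest for Wfdc17 (-4.86), Cxcl9 (-4.82), Serpina3f (-3.87), Saa3 (-3.61) and the invariant chain gene Cd74 (-3.45). Footprint minus RNA values differed from these by over 0.5 in Tmem132e (3.59) and Wfdc17 (-7.06). Nos2 was at -1.75, Il6 at -1.61 and Cfb at 1.82 in the authors' deposited table. In all, 219 genes were higher and 161 lower by at least 1, and 198 and 99 without genes past 5 in any column.

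At 48 h the ribosomal protein medians were smaller, and that of the mitochondrially encoded genes lay below random lists. Small subunit proteins had a median translation efficiency of 0.03 (percentile 80.4) and large subunit proteins of 0.12, which stood apart from random lists (98.0) but neither from matched lists (45.9) nor by the mean (91.8). The difference from 24 h was -0.38 and -0.39, below all random lists. Some members still stood high, such as Rps10 (1.11) and Rpsa (0.53) in the authors' deposited table, as did the study's own set of 16 small subunit assembly genes (median 0.57). The 9 mitochondrially encoded proteins, made on ribosomes inside the mitochondrion, had a median of -0.73, below all random lists, with mt-Nd6 at -1.03 and mt-Co1 at -0.84 in the authors' deposited table. Members that vary together make this percentile uncertain, and whether footprints of those ribosomes were recovered equally in each group was not tested. Nuclear-encoded oxidative phosphorylation subunits had a median of 0.20, above random lists (percentile 99.99), with 12 higher, including Uqcrq (1.42) and Uqcr11 (1.33) in the authors' deposited table.

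At 48 h glycolysis had a median translation efficiency of 0.29, with the lactate transporter gene Slc16a3 at 2.13 in the authors' deposited table, although it fell inside the range of matched lists (percentile 97.4). NF-kB genes had a median of 0.28 (percentile 99.2), with Relb at 1.08 in the authors' deposited table. Mitochondrial ribosomal proteins had 0.15, inside the range of matched lists (86.3). Chemokines (-0.53), interferon-stimulated genes (-0.28) and mitosis (-0.26) lay below. Without genes past 5 in any column, chemokines and interferon-stimulated genes no longer stood apart (percentiles 73.5 and 4.65). Past 1 were 348 genes higher and 209 lower. The extremes in the authors' deposited table were Mip (3.70), the transthyretin gene Ttr (3.26) and Yjefn3 (3.03) at the top, and Cxcl9 (-5.19), Serpina3c (-4.15) and Serpina3f (-3.92) at the bottom. Footprint minus RNA values were farther from 0 for Mip (5.13), Yjefn3 (3.59) and Cxcl9 (-7.22).

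**Figure D4:**
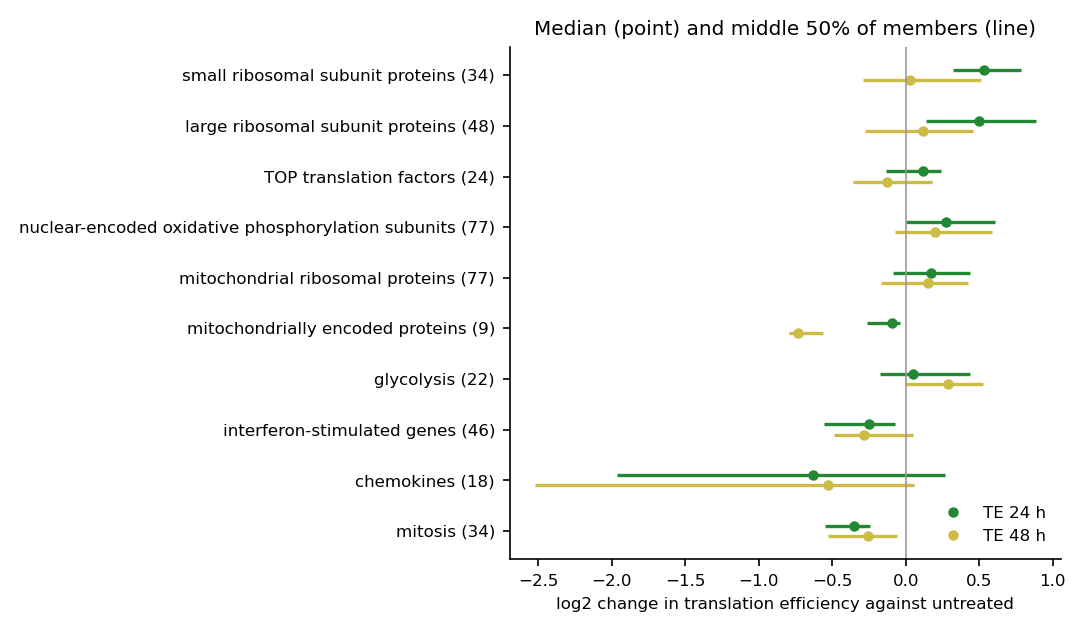
Median log2 change in translation efficiency against untreated cells (point) and interquartile range of the members (line) for 10 gene lists at 24 h and 48 h, with the number of measured members in brackets. Small ribosomal subunit proteins go from 0.53 to 0.03 and mitochondrially encoded proteins from -0.09 to -0.73.

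Of the markers of other brain cell types, the endothelial list of the 4 that were ranked stood apart in RNA at 24 h, and without genes in more than 1 list so did oligodendrocyte markers (percentile 0.15). The other medians also lay below 0, except for microglia (0.18). Endothelial markers (6 genes) had medians of -1.03 at 24 h and -0.91 at 48 h in RNA, and of -1.54 and -1.15 in footprints, with Kdr at -3.54 but Flt1 at 1.77 in the authors' deposited table. Only 4 of 10 ependymal markers and 3 of 18 microglia markers were measured, too few to rank. The 4 had RNA values below 0 at 24 h. They ranged from -0.91 for Cfap126 to -1.41 for the ciliary regulator gene Foxj1 in the authors' deposited table. Among the 3, Cd68 stood at 1.80 and Tmem119 at 0.18 at 24 h in the authors' deposited table, and the third no higher than Tmem119. At 48 h Cd68 stood at 0.56, and the macrophage marker Adgre1, outside this list, at 7.55 in RNA in the authors' deposited table. The share of each cell type was not measured. Oligodendrocyte lineage markers (7) had RNA medians of -0.45 at 24 h and -0.73 at 48 h. Members went both ways, with Cldn11 at -1.92 and Pdgfra at 1.37 in RNA at 24 h in the authors' deposited table. With all 7 the footprint medians lay inside the random range, and without genes in more than 1 list they stood apart (percentiles 0.64 and 2.24). In RNA at 48 h the oligodendrocyte list stood apart by its median and not by its mean (percentile 27.1). Neuron markers (7) had -0.22 at 24 h, inside the random range. Fibroblast and mural markers (13) had a median of -0.08 over members that went both ways, from Dcn at 4.16 to the smooth muscle actin gene Acta2 at -3.01 in the authors' deposited table.

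The study's own 5 gene sets were chosen on these samples and are not independent evidence of their direction. Cytokine activity (74 genes) had RNA medians of 0.55 and 0.52 at 24 h and 48 h, DNA replication (34) -0.58 and -0.52, and apoptosis (67) 0.24 and 0.27, all apart from random lists. The medians of translation efficiency in these 3 sets lay inside the random range at both times. The means of cytokine activity (-0.28 and -0.30) lay below all random lists, and its median at 24 h lay below the range of matched lists (percentile 2.02). Ribosomal small subunit assembly (16) had translation efficiency medians of 0.57 at both times, while the RNA medians were 0.08 and -0.06. Its difference between the times, 0.06, lay inside the random range. Oxidative phosphorylation (75) had 0.30 and 0.22. The authors' deposited sheet of p-values, whose test is not stated there, held 1e-06 and 0.0001 for translation efficiency of small subunit assembly, and 1e-09 and 1e-07 for oxidative phosphorylation. For cytokine activity in RNA the authors' deposited sheet held 5e-09 at 24 h and 3e-10 at 48 h, and in translation efficiency 0.23 and 0.16.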

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

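Of the tests here, those on the RNA libraries alone, on the genes with the largest values and on the gap between deposited and computed translation efficiency were chosen after the result was seen. Since 1 value per gene was deposited, there was no sample to set against its group and no test of a difference between the times, and the patterns below were picked for their size.

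Translation efficiency was higher where genes lie close together: its median went from -0.22 in the tenth of genes with the fewest neighbours to 0.24 in the tenth with the most at 24 h, and from -0.26 to 0.32 at 48 h. Gene span alone is argued against, since within 5 classes of span the lowest rho with density was 0.195 at 24 h. Composition bias in the RNA libraries as the whole cause cannot be told apart. Footprints also correlated with density (rho 0.116 at 24 h and 0.0973 at 48 h), but more strongly with span (-0.219 and -0.179). Their correlation with density was not taken within classes of span. RNA ran the other way with density (-0.0928 and -0.148), so a part from RNA stays open. Against lists matched on density and span, the trend did not account for small and large ribosomal proteins at 24 h (percentiles 99.99 and 100) or oxidative phosphorylation subunits (99.76 at 24 h and 98.1 at 48 h), but could account for large ribosomal proteins at 48 h (45.9) and mitochondrial ribosomal proteins (83.3 and 86.3), although the study's set of 16 small subunit assembly genes, chosen on these samples, stood at 98.9 at 48 h, and small ribosomal proteins at 48 h (16.9) were inside the random range to begin with. Other families of short proteins had a median of 0.21 at 24 h, with a bootstrap interval of 0.05 to 0.29. That interval lies below the 24 h medians of both ribosomal lists, which argues against shortness as the whole account, for these families. How large a part it holds cannot be told apart. The limits set beforehand, 0.27 and 0.25, were a fixed share of the ribosomal medians and lie inside the interval, so the planned test did not decide. The comparison with the full medians was not part of the plan and leaves out the spread of the ribosomal medians. Base composition stays open, as does a biological change in translation of ribosomal protein mRNAs under cytokines.

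Of the 50 genes with the largest RNA values, 45 had a translation efficiency below 0 at 24 h and 44 at 48 h. Picking genes by RNA favours high errors in RNA, and the 50 genes with the largest footprint values tested this: their median was also below 0, at -0.79 (bootstrap interval -1.32 to 0.01) at 24 h and -0.79 (-1.19 to -0.29) at 48 h. At 48 h this argues against selection as the whole cause, and at 24 h the interval includes 0, so selection cannot be told apart from the rest. A candidate explanation is that few footprint reads in untreated cells limit the footprint ratio, but the medians of -1.72 and -1.66 cannot be told apart from a real lag of translation without counts per library. A saturation of translation in the most induced mRNAs is the biological alternative, and was not tested.

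For most genes the deposited translation efficiency equals footprints minus RNA (within 0.1 for 79.5% of genes at 24 h and 78.0% at 48 h), but 34 genes at 24 h and 45 at 48 h differ by over 1. A footprint value pulled toward 0 and a translation efficiency pulled toward 0 predict different outcomes where footprints minus RNA has the sign of RNA, and there translation efficiency plus RNA lay farther from 0 than the footprint value in 30.0% (3 of 10) and 50% (6 of 12), with binomial intervals of 6.67% to 65.2% and 21.1% to 78.9%. Translation efficiency lay nearer to 0 than footprints minus RNA in 61.8% (21 of 34) and 57.8% (26 of 45), with intervals of 43.6% to 77.8% and 42.2% to 72.3%. Among these genes, Pglyrp3 stood at 7.92 in RNA, 0.13 in footprints and -2.24 in translation efficiency at 24 h in the authors' deposited table, and Wfdc17 at 7.11, 0.05 and -4.86. The subset of 10 and 12 genes holds only footprints farther from 0 than RNA, which leaves out genes such as Pglyrp3 and Wfdc17. Over all 34 and 45 genes, translation efficiency plus RNA lay farther from 0 than footprints in 27 and 39. Binomial intervals were 62.1% to 91.3% and 73.2% to 94.9%, but both accounts predict this outside the subset. The intervals of the other tests include 50%, so the accounts cannot be told apart, and no biological explanation was tested.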

How the results depend on the processing

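Of the alternatives here, list means, matched random lists, lists and correlations without genes past 5, and footprint minus RNA values were chosen after the result was seen. A threshold of 1.5 times in place of a log2 value of 1 raised every count, as its construction requires, to 3735 genes in RNA at 24 h, 4130 in RNA at 48 h, 3688 in footprints at 24 h, 3744 in footprints at 48 h, 1886 in translation efficiency at 24 h and 2376 at 48 h, and to 595 in RNA and 736 in footprints between the times. Shifting each column to a median of 0 or leaving out genes past 5 kept each of the 8 total counts within 1.5 times. By direction, leaving out genes past 5 took lower translation efficiency at 24 h from 161 genes to 99, and higher footprints at 48 h against 24 h from 89 to 58. The cause was not tested. No called result reversed under any alternative run. Of the list and comparison pairs, 110 stood apart, and 89 to 113 did so under the alternatives. List means ended 26 calls and added 5, matched lists ended 11 and added 4, leaving out genes past 5 ended 8 and added 2, leaving out genes in more than 1 list ended 3 and added 6, and footprints minus RNA added 3. The calls that ended include translation efficiency of chemokines without genes past 5 (percentiles 91.0 and 73.5) and of large ribosomal proteins at 48 h against matched lists (45.9), and the cause was not tested. Of the study's own set pairs, 19 stood apart, and 18 to 19 under the alternatives. The correlation between RNA and footprints lay between 0.894 and 0.947 at 24 h and 0.877 and 0.944 at 48 h. Of 116 named translation efficiency values, 10 moved by over 0.5 with footprints minus RNA, and none of at least 1 in size changed sign. No paired analysis was possible because 1 value per gene and comparison was deposited, with no value per batch. For the same reason leaving out batches, other variance models, tests of gene sets with an estimated correlation, other pseudocounts or normalizations and other splits of the samples were not run. Centring moves neither percentiles nor correlations, as a constant shift. The depth of the libraries is unknown, so which genes rest on few reads could not be told.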

Other observations

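The gene groups here were put together after the values were seen, as was the test on pseudogenes, whereas the test on neighbouring genes was planned before its result. Acute phase genes (7 measured of 17 written) were among the highest groups, with median RNA values of 5.86 at 24 h and 6.52 at 48 h. The haptoglobin gene Hp stood at 5.86 and the hemopexin gene Hpx at 2.91 in RNA at 24 h in the authors' deposited table. In translation efficiency the 7 had medians of -0.71 and -0.41, below random lists (percentiles 0.02 and 2.21), with 6 of 7 below 0 at 24 h and Hpx apart at 2.02 in the authors' deposited table. The Serpina3 cluster of protease inhibitors (7 genes) had RNA medians of 5.95 and 6.40 and translation efficiency medians of -1.84 and -2.04. Near-identical copies in this family make the split of reads uncertain. All genes with RNA values above 5 and up to 7 had translation efficiency medians of -0.55 at 24 h and -0.46 at 48 h. Those above 7 had -1.74 and -1.66. Random lists hold mostly less changed genes, so the percentiles do not set these groups apart from other genes of like RNA value. Leukocyte adhesion molecules (8), which bind circulating white cells, had RNA medians of 2.56 and 2.34, with Madcam1 at 7.95 and Vcam1 at 4.66 at 24 h in the authors' deposited table. Inflammasome genes (6) had 2.71 and 2.59, with Casp1 at 2.84, and the TNF receptor family (16) 1.25 and 1.21, with Tnfrsf9 at 6.80 and Cd40 at 6.00 at 24 h in the authors' deposited table. Subunits of the constitutive proteasome (31) had medians of 0.37 and 0.29 in RNA and 0.47 and 0.42 in footprints, with 1 member past 1 in RNA at each time. The medians of these 6 groups lay at or above a percentile of 99.68 in RNA and footprints. Not every written gene was measured: 7 of 11 in the Serpina3 cluster, 8 of 12 adhesion molecules, 6 of 12 inflammasome genes and 16 of 22 TNF receptors. If genes silent in untreated cells entered the deposited values only when induced, such medians lie too high.

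Type IV collagens (6), which build basement membranes, had RNA medians of -0.14 and 0.01, inside the random range. Col4a3 and Col4a4, neighbours read in opposite directions, were lower, at -3.25 and -3.33 at 24 h and -4.64 and -4.35 at 48 h in the authors' deposited table. Lysosomal proteins (30) had RNA medians of 0.11 and 0.08, inside the random range, while their footprint difference of 48 h against 24 h (0.18) lay above it (percentile 99.97). Short protein families (67) had RNA medians of 0.00 and 0.03, inside the random range, and translation efficiency medians of 0.21 and 0.05, the first above it (99.99) but not against lists matched on gene density and span (89.3). Their difference between the times in translation efficiency (-0.14) lay below all random lists, as did those of the ribosomal proteins.

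Many induced genes were neighbours. Of the 278 genes with a position and an RNA value of at least 3 at 24 h, 63 pairs were adjacent among the measured genes, where 1000 random gene sets gave 0 to 15 with a median of 6, which argues against chance placement. There were 11 runs of 3 or more genes, holding 49 genes. On GRCm38.p6 they included Gbp8 to Gbp6 on chromosome 5 (105012513 to 105295871), Cxcl9 to Cxcl11 on chromosome 5 (92321331 to 92363296), the Serpina3 cluster on chromosome 12 (104146907 to 104394259) and the interferon-induced genes from Pyhin1 to Ifi205 on chromosome 1 (173630859 to 174031755). Tandem duplicates may share both regulation and reads, and neither was tested, as the 63 pairs concern placement alone.

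Some of the induced genes are annotated as pseudogenes on the reference, which is of the C57BL/6 strain. The prediction for a lack of a protein-coding copy was that each would lie below the genes of like RNA value in translation efficiency. At 24 h 5 of 8 did, or 6 of 8 by footprints minus RNA. These values are changes against untreated cells, which would lack the copy too, so the counts do not decide on that explanation. Cxcl11 (-3.33), Mx1 (-1.72) and Serpina3h (-3.21) were among the 5 in the authors' deposited table, while Oas1b (0.82) and BC023105 (0.66) lay above. Serpina3e-ps also lay above at 0.09 in the authors' deposited table, although its values of 3.53 in RNA and 0.69 in footprints place it below by footprints minus RNA. The chemokine gene Cxcl11 is listed as a transcribed pseudogene in RefSeq.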
